A study of Mus musculus and Homo sapiens with 36 samples.

How the data were processed

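The series holds SNARE-seq data, in which polyadenylated RNA and accessible chromatin of the same nucleus share a barcode. Samples were human cell lines mixed in 1 library (BJ, H1, K562, GM12878), P0 mouse cerebral cortex (5 labelled replicates) and adult mouse cerebral cortex of 2 months (12 labelled replicates), each with an RNA and a chromatin library. The authors deposited count matrices with no normalization: UMI counts per gene and nucleus, and chromatin fragment counts per peak and nucleus. Names of barcodes, genes and peaks, as the authors deposited them, are text with no unit. Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.5 and Picard were used with the builds mm10 and hg38, with no role or order given. RNA followed the Drop-seq protocol, and captured chromatin fragments were amplified and size-selected. The counting tool, the peak caller and the filter on nuclei were not stated. All deposited nuclei had at least 200 detected genes.

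Adult barcodes carry 1 of 12 prefixes, taken as 12 libraries and called A to L here, since which prefix is which labelled replicate was not stated. P0 barcodes carry none, so P0 was 1 pooled sample, and the mixture was 1 sample. Libraries were not stated to come from separate animals, so p-values measure the spread between these libraries. Some known markers of the marker lists are not reported singly here (Sox2, Neurod1, Dlx6os1, C1qa, Slco1a4, Col1a1, HBG1, HBE1, BANK1 and SOX2).

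Adult cortex gave 10309 nuclei (785 to 916 per library) with 15969442 UMIs (1139094 to 1623072 per library), a median of 1332 UMIs per nucleus (1134.5 to 1589 between libraries) and a median of 2256 chromatin counts. P0 cortex gave 5081 nuclei with 2185244 UMIs and medians of 357 UMIs and 2583 chromatin counts. The mixture gave 1047 nuclei with 652674 UMIs and medians of 508 UMIs and 805 chromatin counts. Tables held 33160, 19322 and 18666 genes and 244544, 229429 and 136771 peaks. Of nonzero chromatin entries 6.80%, 10.3% and 5.17% were above 1.

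Nuclei with at least 200 UMIs and 200 chromatin counts were kept. Scrublet through scanpy 1.11.5 (expected rate 6%) marked 96 adult nuclei (0.931%) and 43 of the mixture (4.11%), which were removed. It marked 2 of 5081 P0 nuclei, far from the expected rate, so its calls were not used there and doublets remain in the P0 values. RNA counts were scaled to 1000 per nucleus and logged, 2000 variable genes were reduced to 30 principal components, and 15 nearest neighbours were clustered with Leiden at resolution 1 (leidenalg 0.10.2, seed 1). All genes of the readout lists (191 adult, 145 P0, 74 mixture) were left out of the clustering, so that their levels are a readout. Chromatin was clustered on its own (peaks in at least 50 nuclei, TF-IDF, truncated SVD with scikit-learn 1.9.0, Leiden).

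RNA clusters were named from marker lists by a score with a minimum of 0.55 and a gap of 0.3 to the next type, a ratio of 1.5 and 3 markers, or a score of 0.4 with a marker among the 10 top genes, and for layers a score of 0.3 and a gap of 0.5. These thresholds were set after the clusters were seen and before any result was computed. The marker and readout lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be chosen later. Names carry "-like" since no label assigns nuclei to types. At P0 no cluster took the names intermediate progenitor, astrocyte, oligodendrocyte precursor, microglia, endothelial, mural or fibroblast.

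Peaks were assigned to genes by overlap with the gene body and 2 kb on both sides, since the annotation holds no strand. Of 33160 adult gene names 26669 (80.4%, with 98.6% of UMIs) matched the mm10 annotation, 978 of them through an older symbol, and 20582 had a peak, while 63.7% of peaks lay in a window and 4.24% in more than 1. At P0 17338 of 19322 names (89.7%) matched. No hg38 annotation was used, so chromatin of the mixture was clustered only. P0 and adult RNA were compared over 19193 shared genes.

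For the 3 adult comparisons (GABAergic-like minus glutamatergic-like, oligodendrocyte-like minus astrocyte-like, deep-layer-like minus upper-layer-like) counts were summed per library and class, with at least 10 nuclei in each. The sums held 36 to 70 GABAergic-like, 642 to 788 glutamatergic-like, 15 to 34 oligodendrocyte-like, 29 to 47 astrocyte-like, 127 to 188 deep-layer-like and 318 to 409 upper-layer-like nuclei. The smallest sums of RNA were 57515 UMIs for neurons, 16116 for glia and 180040 for layers. EdgeR 4.0.16 in R 4.3.3 fitted quasi-likelihood models with the library as a block, after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment at 0.05. Values are log2 differences ± SE (the log2 difference over the square root of F) with mean CPM over 12 libraries. RNA counts cover genes that did not serve for clustering. Fixed lists with at least 3 tested members went through camera (limma 3.58.1) with a preset correlation of 0.01, and beside it with an estimated correlation and fry. Of 83 list tests 33 passed with the preset and 28 with the estimated correlation. Fry asks whether a list moves on balance in 1 direction and does not compare it with other genes.

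Single samples have no test: class sums are given as CPM with exact Poisson 95% intervals, shares with Wilson intervals, and ratios with exact conditional intervals, all of which cover counting error only. A fold against 0 counts uses a floor of 3 counts in the class and is written as a lower bound. P0 values were set beside the range of the 12 adult libraries. The list members named are the 3 with the highest CPM among those past the threshold in the list's direction and up to 2 against it, or without a test the 3 with the highest CPM and the 1 furthest against. Outside the lists the 5 genes and 3 peaks with the largest fold each way among those with at least 50 counts and the same direction in 75% of libraries are named, for age the 10 highest and 10 lowest ratios among genes with at least 100 UMIs, and for each line the 5 highest ratios among genes with at least 50 UMIs. Ribosomal protein genes and unnamed gene models were not named, and some genes that the rule picks are not reported here, though list counts, sums and tests include them.

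Each fit was tested on simulated data with 200 changed features, a spread between libraries of 0.1 and the depths of the real sums, and recovery was counted over the changed features that passed the filter. At a fold of 4 it recovered 98.1%, 97.5% and 96.8% of changed features for neurons (RNA, gene windows, peaks) and 100% for glia and layers. At a fold of 2 it recovered 69.7%, 77.3% and 34.8% for neurons, 100% for glia (over only 10, 7 and 3 features) and 100%, 100% and 96.4% for layers. False calls made up 1%, 6.80% and 2.56% of calls for neurons, 8.57%, 15% and 6.25% for glia and 3.25%, 2.99% and 2.99% for layers. The simulated spread of 0.1 was shared by both classes of a library, so it did not vary the class difference. That difference varied only through 1 common dispersion for all features, so features with a larger spread were not covered. The alternatives were no library block, RLE size factors or TMM where the main scaling was by totals, no filter on low counts, doublets kept, resolution 2 or 0.5, 15 components, a minimum of 500 UMIs, chromatin counts above 1 set to 1, DESeq2 1.42.0, other overlap rules for peaks, and, chosen after seeing the data, leaving out library G and thinning counts to the smaller class. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9 and Matrix 1.6.5.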

Results

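SNARE-seq reads messenger RNA and accessible chromatin from the same nucleus. Across 12 adult mouse cortex libraries, glutamatergic-like neurons made up 83.3% ± 1.69 of the nuclei (mean ± SD, n = 12). GABAergic-like neurons made up 6.29% ± 1.21, astrocyte-like nuclei 4.27% ± 0.885, oligodendrocyte-like nuclei 2.89% ± 0.752, precursors of oligodendrocytes 1.097% ± 0.301 and microglia-like nuclei 1.02% ± 0.431. Upper-layer-like neurons, which in the cortex project mainly to other cortical areas, held 44.3% ± 2.11 of all nuclei. Deep-layer-like neurons, which include the cells that project out of the cortex, held 17.6% ± 1.72. At a minimum of 500 UMIs the glutamatergic-like share was 77.2% ± 1.33, because 9.50% ± 1.06 of nuclei then stayed unnamed against 1.18% ± 0.336. No adult cluster took the name of endothelial, mural or fibroblast cells.

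How far an RNA class gathered in 1 cluster made from chromatin alone, with no use of the RNA, differed by cell type. In adult cortex 93.9% ± 3.00 of GABAergic-like nuclei sat in 1 of 13 chromatin clusters, and they made up 80.5% of that cluster. Astrocyte-like nuclei placed 78.0% ± 13.3 of their number in 1 cluster, deep-layer-like nuclei 66.3% ± 15.9 and upper-layer-like nuclei 34.5% ± 8.98. They made up 76.7%, 87.1% and 88.1% of these clusters. Upper-layer-like nuclei were spread mainly over the chromatin clusters numbered 0, 1 and 4 (1556, 1530 and 835 of 4522 nuclei). Their low share in 1 cluster therefore does not show that chromatin followed this class less. Oligodendrocyte-like, precursor-like and microglia-like nuclei shared 1 chromatin cluster, with 56.7% ± 12.9, 51.0% ± 20.6 and 53.6% ± 27.9 of their nuclei in it. The adjusted Rand index between RNA and chromatin clusters, which is 1 for identical groupings and near 0 for unrelated ones, was 0.505 ± 0.0597 per adult library (n = 12), 0.216 in newborn (P0) cortex and 0.241 in the cell line mixture. At a minimum of 500 UMIs it was 0.116 at P0 and 0.152 in the mixture, and at resolution 0.5 it was 0.328 at P0. Library G stood apart at 0.334, while the other 11 libraries lay between 0.468 and 0.556 (0.521 ± 0.0272), but not at resolution 0.5, where it was at 0.542 and library J lower at 0.535. With the named classes in place of the RNA clusters, the index was 0.0853 ± 0.0106 in the adult (n = 12), 0.320 at P0 and 0.241 in the mixture. The order of the 3 data sets thus depends on which RNA grouping is used. The named groupings are also of unlike fineness, so their indices are not directly comparable. In the adult 1 class, glutamatergic-like neurons, held 8508 of 10213 nuclei, while at P0 the names split these neurons by layer. In the mixture both groupings gave the same index.

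**Figure D1:**
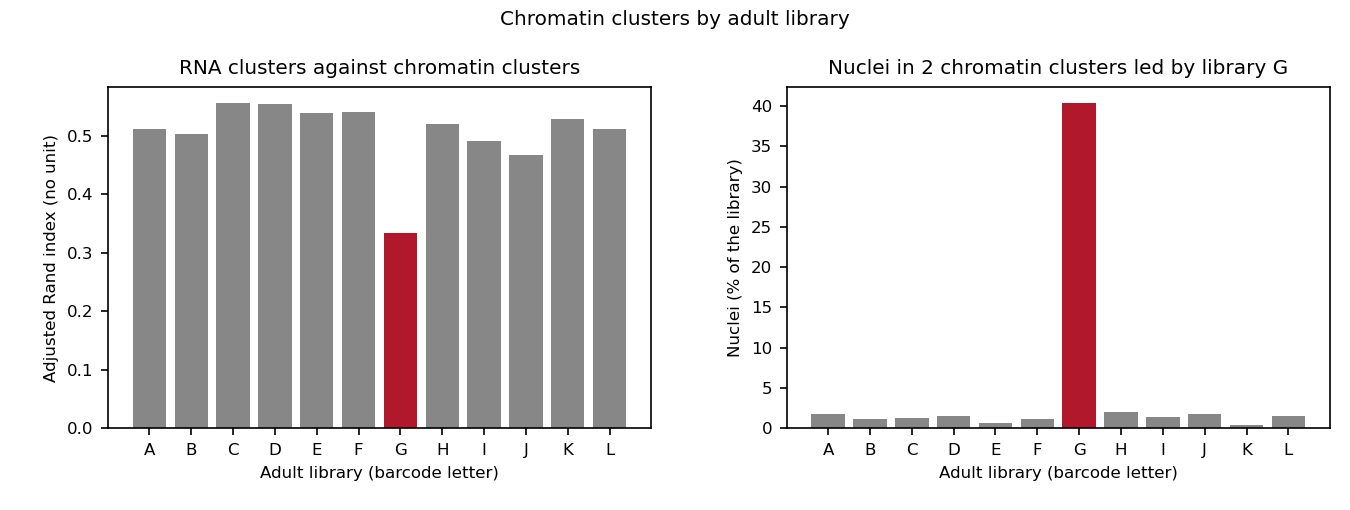
Left, adjusted Rand index between RNA and chromatin clusters (no unit) for each of the 12 adult libraries, 1 bar each. Right, percent of each library's nuclei in the 2 chromatin clusters that library G leads: 40.4% in G and 1.35% ± 0.472 in the other 11.

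The human mixture held K562 (chronic myeloid leukaemia, erythroid features), GM12878 (B lymphoblastoid), H1 (embryonic stem cells) and BJ (skin fibroblasts), and each line's class carried the programme of its lineage. B cell genes reached 9539 CPM (counts scaled to the total of the class) in the GM12878-like class against 150 in the K562-like class, the highest other, a ratio of 63.8 (95% interval 38.9 to 112). Erythroid genes were 20.7 times higher in the K562-like class than in the H1-like class (1178 against 56.8 CPM, interval 11.7 to 40.0). Pluripotency genes were 19.03 times higher in the H1-like class (5337 against 280 CPM, interval 13.3 to 28.3). Genes of the fibroblast matrix were 8.14 times higher in the BJ-like class (18893 against 2321 CPM, interval 7.44 to 8.92). None of these genes had served to make or name the clusters. Intervals here are exact conditional intervals for Poisson counts and cover counting error only, since 1 library gives no spread between replicates and no test.

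A list gene counted as detected with at least 3 UMIs over the compared classes. Of 16 B cell genes 14 were detected, and all 14 were highest in the GM12878-like class. HLA-DRB1 and HLA-DPA1, which present antigen to T cells, were 59.3 times (30.8 to 131) and 80.7 times (27.0 to 397; 3 UMIs in the other class) higher. IRF4, a transcription factor of activated B cells, was 39.8 times higher (12.3 to 205; 3 UMIs). All 14 detected pluripotency genes were highest in the H1-like class. They were led by the telomere protein gene TERF1 at 2430 CPM (20.9 times, 9.56 to 57.3), the Wnt modulator SFRP2 (71.4 times, 24.1 to 349; 3 UMIs) and the DNA methyltransferase gene DNMT3B (5.50 times, 3.05 to 10.9). All 15 fibroblast genes were highest in the BJ-like class. Among them were the matrix genes SPARC (8.19 times, 6.80 to 9.95) and COL6A3 (20.1 times, 11.9 to 37.0) and the actin-binding CALD1 (3.91 times, 3.30 to 4.66). Of 9 detected erythroid genes 8 were highest in the K562-like class. RHAG, part of the Rh complex of the red cell membrane, was 74.8 times higher (19.96 to 630; 2 UMIs in the H1-like class). MYB reached 112 CPM against 1 UMI (5.80 times, 0.858 to 248), and NFE2 was at least 1.77-fold higher than in a class with 0 UMIs. The erythropoietin receptor gene EPOR lay at 9.35 CPM below 21.9 in the H1-like class (0.428 times, 0.00904 to 3.82).

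K562 carries the BCR-ABL1 fusion. BCR and ABL1 together reached 215 CPM in the K562-like class against 101 in the H1-like class (2.14 times, 1.15 to 3.99). The interval included 1 with TMM scaling (1.76 times, 0.945 to 3.29) and at a minimum of 500 UMIs (1.32 times, 0.580 to 2.85). ABL1 alone was 4.76 times higher (187 against 39.3 CPM, 2.07 to 11.9), while BCR, with 3 UMIs, was not (0.428 times, 0.0794 to 1.51). Cell cycle genes were highest in the H1-like class (2898 against 1703 CPM in the GM12878-like class, 1.70 times, 1.36 to 2.15; 10 of 12 genes), and at a minimum of 500 UMIs the interval included 1 (1.198 times). The mitotic genes CENPF (2.56 times, 1.63 to 4.19) and CCNB1 (3.23 times, 1.71 to 6.75) and the replication clamp gene PCNA (1.17 times, 0.690 to 2.10) led this list. For TOP2A the interval included 1 (0.668 times the GM12878-like class, 0.416 to 1.11).

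Among genes outside the clustering with at least 50 UMIs in all, the highest ratios in the K562-like class after RHAG belonged to CREG1 (6.84 times, 3.77 to 13.2), NUP214 (5.19, 2.71 to 10.5), FANCI (5.07, 1.84 to 19.5) and OXLD1 (4.19, 1.28 to 21.6). In the GM12878-like class CALM3 (3.16, 1.82 to 5.44), MYCBP2 (2.89, 1.40 to 5.78) and the RNA editing enzyme gene ADAR (2.88, 1.32 to 6.08) followed the HLA genes. The H1-like class had the neural genes UNC5D (23.4 times, 6.31 to 196; 2 UMIs) and GPM6B (14.5, 5.37 to 55.0) beside SFRP2 and TERF1. The BJ-like class had CTHRC1 (86.9, 15.2 to 3472; 1 UMI), ACKR4 (36.5, 9.74 to 307; 2 UMIs), the collagen gene COL5A2 (33.0, 13.8 to 103), the fibroblast activation protein gene FAP (31.5, 15.1 to 79.4) and THBS1 (30.9, 19.6 to 51.6). H1-like nuclei made up 37.6% of the 1004 nuclei (Wilson 95% interval 34.7 to 40.7), BJ-like 30.6% (27.8 to 33.5), K562-like 19.1% (16.8 to 21.7) and GM12878-like 12.6% (10.7 to 14.8; 6.48% at a minimum of 500 UMIs). By chromatin alone 92.2% of BJ-like nuclei (88.6 to 94.7) were in 1 cluster, which was 67.5% BJ-like, while GM12878-like (48.0%) and K562-like nuclei (41.1%) had the same leading cluster and H1-like nuclei placed 32.8% in theirs, which was 75.6% H1-like.

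In adult cortex the transcripts that separate inhibitory from excitatory neurons differed widely between the classes. GABAergic readout genes summed to 8540 ± 1157 CPM in GABAergic-like nuclei and 749 ± 30.2 CPM in glutamatergic-like nuclei, a ratio of 11.4 (12 of 12 libraries). Glutamatergic readout genes were 2.80 times lower in GABAergic-like nuclei (780 ± 122 against 2188 ± 111 CPM, 12 of 12 libraries). The RNA editing homologue Adarb2, found in interneurons derived from the caudal eminence, was 4.84 ± 0.07 (SE) higher on the log2 scale (2457 against 81.5 CPM). The glutamate receptor scaffold Grip1 was higher by 3.28 ± 0.07 and the potassium channel Kcnc2, which lets interneurons fire fast, by 2.42 ± 0.06. The actin regulator Baiap2 was lower in GABAergic-like nuclei, at -2.37 ± 0.16 (63.5 ± 24.3 against 329 ± 19.3 CPM), as were Chn1 (-0.91 ± 0.13) and Mical2 (-0.83 ± 0.09), each in 12 of 12 libraries by TMM-scaled CPM (11 of 12 for Chn1 by CPM of the class total).

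All 9 tested GABAergic readout genes were higher (9 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 2.3e-35, median log2 4.34). All 12 glutamatergic ones were lower (12 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 3.7e-14, median log2 -2.23). Of 5 upper-layer genes 4 were lower in GABAergic-like nuclei (4 adjusted over the list alone), with the summed level lower in 12 of 12 libraries (camera, Benjamini-Hochberg adjusted p = 0.000325). Among them were the activity-dependent transcription factor Mef2c (-0.82 ± 0.07), Lamp5 (-1.45 ± 0.19) and Kcnh5 (-1.64 ± 0.17). Of 7 deep-layer genes 5 were lower and 1 higher (5 and 1 adjusted over the list alone). This call was lost with another variance assumption: the camera Benjamini-Hochberg adjusted p = 0.0448 (median log2 -0.85, summed level lower in 12 of 12 libraries) became adjusted p = 0.149 with an estimated correlation. Ldb2 (-1.36 ± 0.15), Tshz2 (-0.85 ± 0.24) and Zfpm2 (-0.57 ± 0.13) were lower. Sox5 was higher at 0.26 ± 0.10 (edgeR, Benjamini-Hochberg adjusted p = 0.0366, 10 of 12 libraries) and stood at -0.01 without the filter on low counts.

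Genes shared by all neurons moved both ways. Among 12 synaptic vesicle genes 5 were lower in GABAergic-like nuclei, including the membrane fusion genes Snap25 (-0.72 ± 0.07) and Stx1a (-1.58 ± 0.15) and the calcium sensor gene Syt1 (-0.18 ± 0.05). In the same list 3 were higher, including Sv2a (0.75 ± 0.13), with 5 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.245, median log2 -0.13, summed level lower in 12 of 12 libraries). Syn2 was higher at 0.25 ± 0.10 (edgeR, Benjamini-Hochberg adjusted p = 0.0457, 8 of 12 libraries). Without library G it was at 0.21 and no longer passed (adjusted p = 0.131, edgeR with Benjamini-Hochberg), and without the filter on low counts it was at -0.01. Among 15 voltage-gated channel genes 4 were higher, with Kcnc2 and Scn1a (0.36 ± 0.09). Another 7 were lower, with Cacna1e (-1.19 ± 0.09) and Kcnq3 (-0.21 ± 0.07), also 4 and 7 adjusted over the list alone. The median of this list was -0.07 and the mean 0.21, opposite in sign (camera, Benjamini-Hochberg adjusted p = 0.441, summed level higher in 12 of 12 libraries). The summed level was 8050 ± 756 CPM against 6485 ± 184 CPM in glutamatergic-like nuclei. Kcnc2, also a GABAergic readout gene, gave 1949 ± 361 and 352 ± 30.6 CPM of these sums. The higher sum thus rested on this 1 gene. Of 6 cholesterol synthesis genes 1 was lower (1 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.245, summed level lower in 9 of 12 libraries). In all, 1764 of 6777 tested genes that had not served for clustering passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 750 higher and 1014 lower in GABAergic-like nuclei. RNA tests between classes made from RNA are partly circular, and the count was 605 when glutamatergic-like counts were thinned to the depth of the GABAergic-like class.

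The chromatin of the same nuclei, which played no part in making the classes, was most open in GABAergic-like nuclei at the genes of interneuron identity. Counts over the gene body and 2 kb on either side were 3.98 ± 0.29 higher on the log2 scale at Dlx6 (56.9 against 3.33 CPM; chromosome 6, 6863334 to 6867970, mm10) and 3.88 ± 0.32 higher at Dlx1 (chromosome 2, 71528113 to 71533981), homeobox genes that specify cortical interneurons. Slc32a1, the transporter that loads GABA into vesicles, was 3.82 ± 0.26 higher (72.3 against 4.75 CPM; chromosome 2, 158607260 to 158615747), and Gad1, which makes the enzyme of GABA synthesis, 2.26 ± 0.21 higher (72.7 against 14.9 CPM). Neurod2, a transcription factor of excitatory neurons, was lower at -2.71 ± 0.44 (4.24 against 27.9 CPM). All of these held in 12 of 12 libraries. Dlx1as (3.93 ± 0.31) and Dlx6os2 (3.90 ± 0.36) overlap Dlx1 and Dlx6, and peaks carry no strand, so signal within each pair cannot be assigned to 1 gene. The other largest decreases were at Spata21 (-2.20 ± 0.48), Tmem61 (-2.07 ± 0.42), Sln (-1.79 ± 0.45) and Spesp1 (-1.77 ± 0.25).

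The marker lists used to name classes from RNA were open in the matching class. All 4 tested GABAergic markers were higher (4 adjusted over the list alone), with Gad1, Nxph1 (1.43 ± 0.16) and the neuregulin receptor gene Erbb4 (1.19 ± 0.16), with a summed level higher in 12 of 12 libraries (camera, Benjamini-Hochberg adjusted p = 4.2e-17). All 6 glutamatergic markers were lower (6 adjusted over the list alone), with the vesicle gene Sv2b (-1.10 ± 0.10), Arpp21 (-0.81 ± 0.09) and the kinase gene Camk2a (-0.71 ± 0.10), by camera at a Benjamini-Hochberg adjusted p = 1.6e-15 (median log2 -0.86, 12 of 12 libraries). Among readout genes 10 of 11 GABAergic ones were higher (10 adjusted over the list alone), with Sox6 (1.07 ± 0.16), Adarb2 (0.46 ± 0.15) and Grip1 (0.41 ± 0.09). Of 12 glutamatergic ones 10 were lower (11 lower and 1 higher adjusted over the list alone), with Ptk2b (-0.76 ± 0.09), Baiap2 (-0.56 ± 0.09) and Mical2 (-0.19 ± 0.07). Camera gave these readout lists Benjamini-Hochberg adjusted p = 4.0e-19 (median log2 1.24) and 5.9e-09 (median log2 -0.75), each in 12 of 12 libraries by summed level.

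By camera over gene windows, layer readout genes, upper-layer markers and astrocyte markers were less open in GABAergic-like than in glutamatergic-like nuclei, while most other glial lists did not pass. Of 11 upper-layer readout genes 6 were lower (7 adjusted over the list alone), with Lhx2 (-1.52 ± 0.22), Kcnh5 (-0.55 ± 0.15) and Mef2c (-0.36 ± 0.08; camera, Benjamini-Hochberg adjusted p = 6.1e-05, 12 of 12 libraries). Of 11 deep-layer readout genes 7 were lower (8 adjusted over the list alone), with Ldb2 (-0.56 ± 0.12), Sox5 (-0.24 ± 0.08) and Thsd7b (-0.37 ± 0.13), by camera at a Benjamini-Hochberg adjusted p = 0.00029 (12 of 12 libraries). Thsd7b no longer passed without library G (-0.27, edgeR with Benjamini-Hochberg, adjusted p = 0.148). Of 6 upper-layer naming markers 3 were lower, Rorb (-1.04 ± 0.15), Stard8 (-0.79 ± 0.22) and Cux1 (-0.26 ± 0.09), and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0122, 12 of 12 libraries). Deep-layer markers split, with Foxp2 (-1.18 ± 0.21) and Hs3st4 (-0.78 ± 0.13) lower and Bcl11b (0.62 ± 0.11), a factor also used by interneurons, higher. These were 2 and 1 adjusted over the list alone as well (camera, Benjamini-Hochberg adjusted p = 0.252, summed level lower in 8 of 12 libraries). Astrocyte markers were lower for 3 of 4 (Slc1a2 -0.88 ± 0.11, Gpc5 -0.95 ± 0.14; 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 1.8e-05, 12 of 12 libraries). The astrocyte readout list of 12 split. Aldh1l1 (-0.74), Bmpr1b (-0.75), Gli3 (-0.88) and 1 more were lower, and Sox9 (0.62) and Aldoc (0.67) higher (4 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.252, summed level lower in 11 of 12 libraries).

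Synaptic vesicle genes were lower for 4 of 12, with Syt1 (-0.29 ± 0.06) and Cplx2 (-0.40 ± 0.09). They were 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0419, median log2 -0.14, 12 of 12 libraries; adjusted p = 0.121 with an estimated correlation). Channel genes were lower for 6 of 15, with Cacna1e (-0.70 ± 0.07) and Scn8a (-0.39 ± 0.09). Kcnc2 (0.64 ± 0.21) and Kcna1 (0.59 ± 0.16) were higher, against 6 lower and 3 higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0419, median log2 -0.07, 12 of 12 libraries; adjusted p = 0.0699 with an estimated correlation). Mural markers were lower for 2 of 3, Pdgfrb (-1.23 ± 0.25) and Cspg4 (-0.58 ± 0.16), both also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0419, 12 of 12 libraries; adjusted p = 0.0834 with an estimated correlation). By camera no direction passed for cholesterol synthesis (Dhcr7 0.35 higher and 1 lower, of 12), oligodendrocyte readout (Tspan2 1.05 higher, Enpp2 -0.40 lower, of 5), oligodendrocyte markers (Mbp -0.38 lower, of 4), precursor markers (Cspg4 lower, of 5) or fibroblast markers (Bnc2 -1.29 lower, of 3). Adjusted over the list alone these calls were 1 and 1, 1 and 1, 2, 2 and 1. No direction passed for endothelial markers either, where edgeR called 0 of 3 genes, with 1, Flt1, lower adjusted over the list alone and at an unadjusted p under 0.05.

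By edgeR's quasi-likelihood test 2952 of 14188 genes passed at a Benjamini-Hochberg adjusted p under 0.05 (1199 higher, 1753 lower), and 4643 of 18900 peaks (1289 higher, 3354 lower). The peak with the largest increase lay in Slc32a1 and the overlapping gene model Gm14204 (chromosome 2, 158610484 to 158611156, mm10; 4.21 ± 0.29, 42.4 against 2.10 CPM). The next were a peak outside gene bodies (chromosome 6, 115043708 to 115044307; 4.18 ± 0.32) and one in Dlgap2 (chromosome 8, 14689573 to 14690338; 3.72 ± 0.28). The largest decreases lay in Gramd4 (chromosome 15, 86065381 to 86065929; -3.05 ± 0.60), Cdk5rap2 (chromosome 4, 70258239 to 70258653; -2.95 ± 0.61) and Myo18b (chromosome 5, 112785982 to 112786456; -2.91 ± 0.61). Peaks of glutamatergic readout genes were lower for 15 of 38 (19 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.000105, median log2 -0.75). Peaks of glutamatergic markers were lower for 13 of 26, with 1 higher (16 and 1 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.000205, median log2 -0.88). Peaks of astrocyte markers were lower for 5 of 8 (6 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0047, median log2 -1.09). Peaks of GABAergic readout genes were higher for 2 of 7 (3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0185, median log2 0.44; adjusted p = 0.0562 with an estimated correlation). Peaks of upper-layer readout genes (4 of 15 lower, 4 adjusted over the list alone), deep-layer readout genes (2 lower and 1 higher of 12, also adjusted over the list alone) and upper-layer markers (6 lower and 1 higher of 13, or 6 and 2 adjusted over the list alone) did not pass (camera, Benjamini-Hochberg adjusted p = 0.1597, 0.381 and 0.137). With RLE size factors the split of peaks was 589 higher and 4665 lower, with the median of all peaks at -0.19. With counts thinned to the smaller class 804 genes and 3 peaks passed.

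Oligodendrocyte-like and astrocyte-like nuclei differed most in the genes of their own lineages. Oligodendrocyte readout genes summed to 4897 ± 868 CPM in oligodendrocyte-like and 196 ± 97.0 CPM in astrocyte-like nuclei, 25.0 times higher in 12 of 12 libraries. Astrocyte readout genes were 15.2 times higher in astrocyte-like nuclei (8261 ± 1057 against 545 ± 227 CPM), and cholesterol synthesis genes 2.90 times (954 ± 190 against 329 ± 180 CPM), each in 12 of 12 libraries. On the log2 scale the neurotensin receptor gene Ntsr2 was at -5.28 ± 0.30 in oligodendrocyte-like nuclei (42.7 against 1543 CPM). The lipid phosphatase gene Plpp3 was at -4.88 ± 0.26 (47.0 against 1452 CPM) and Glul, whose enzyme makes glutamine from glutamate, at -2.34 ± 0.23 (155 against 769 CPM), each in 12 of 12 libraries. All 5 tested astrocyte readout genes were lower (5 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 7.0e-05, median log2 -4.88). Neuronal lists also differed in sum: synaptic vesicle genes were 1.51 times higher in oligodendrocyte-like nuclei (12 of 12 libraries), channel genes 1.31 times (11 of 12) and glutamatergic readout genes 1.45 times (10 of 12), while GABAergic readout genes were lower (0.809 times, 10 of 12).

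In chromatin, Mbp, the gene of myelin basic protein, was more open in oligodendrocyte-like nuclei by 1.05 ± 0.16 (384 against 178 CPM) and Prdm16, a transcription factor of astrocytes and their precursors, less open at -1.56 ± 0.17 (132 against 411 CPM), each in 12 of 12 libraries. Increases followed at Mylpf (0.98 ± 0.19) and Tbc1d10b (0.82 ± 0.17), which share a peak, Dscaml1 (0.89 ± 0.15) and Itpk1 (0.83 ± 0.18). Decreases followed at the RNA-binding gene Msi2 (-1.49 ± 0.17), Hk1 (-1.07 ± 0.20), Pitpnc1 (-1.06 ± 0.18) and Cpe (-0.95 ± 0.21). Summed levels of the glial lists went with their own class, each in 12 of 12 libraries: oligodendrocyte markers 2.47 times and readout genes 2.67 times higher in oligodendrocyte-like nuclei, astrocyte markers 1.87 times and readout genes 2.48 times higher in astrocyte-like nuclei. Upper-layer readout genes were 1.30 times higher in astrocyte-like chromatin (11 of 12 libraries) and 1.24 times higher in oligodendrocyte-like RNA (10 of 12), with no test of either. Chromatin sums of the synaptic vesicle, cholesterol synthesis and GABAergic readout genes differed by 1.04, 1.096 and 1.04 times between the glial classes (same direction in 9, 8 and 7 of 12 libraries). These sums were not tested, so no direction is given. In RNA the synaptic vesicle genes were 1.51 times higher in oligodendrocyte-like nuclei (12 of 12), and the other lists 2.90 times (12 of 12) and 1.24 times (10 of 12) higher in astrocyte-like nuclei. By camera the glutamatergic readout and channel lists did not pass (Benjamini-Hochberg adjusted p = 0.953 for each; median log2 0.21 and 0.04, the latter opposite in sign to its mean). EdgeR called 0 of 3 genes of the first list, or 1 higher and 1 lower adjusted over the list alone and 2 at an unadjusted p under 0.05. It called 0 of 4 of the second, 0 of them adjusted over the list alone or at an unadjusted p under 0.05.

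By edgeR at a Benjamini-Hochberg adjusted p under 0.05, 155 of 242 tested genes passed in RNA (93 higher and 62 lower in oligodendrocyte-like nuclei), 66 of 769 in chromatin (32 and 34) and 4 of 102 peaks (3 and 1). The higher peaks were the one shared by Mylpf and Tbc1d10b (chromosome 7, 127208537 to 127209522, mm10; 0.86 ± 0.19), one outside genes (chromosome 13, 9011697 to 9011890; 0.83 ± 0.14) and one in Lars2 (chromosome 9, 123461870 to 123462255; 0.79 ± 0.15). The lower one lay in Garem (chromosome 18, 21299741 to 21300732; -0.58 ± 0.19; edgeR, Benjamini-Hochberg adjusted p = 0.0498, 11 of 12 libraries). The Garem peak did not pass in any of the 7 alternative fits that tested it, the one without library G included (-0.57). DESeq2 called 31 genes in chromatin (10 higher, 21 lower), and with counts above 1 set to 1 edgeR called 0 of 19 tested peaks (3 at an unadjusted p under 0.05). These 292 and 433 nuclei gave 15 to 47 nuclei per class and library, so few features had the counts to be tested.

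Deep-layer-like and upper-layer-like neurons differed in the genes that mark cortical depth. Deep-layer readout genes summed to 2433 ± 212 CPM in deep-layer-like and 626 ± 37.8 CPM in upper-layer-like nuclei, 3.89 times higher, and upper-layer readout genes were 2.36 times higher in upper-layer-like nuclei (2553 ± 106 against 1081 ± 85.1 CPM), each in 12 of 12 libraries. Zfpm2, a cofactor of GATA factors, was higher in deep-layer-like nuclei by 2.66 ± 0.06 (698 against 110 CPM), Sox5, which guides the fate of corticofugal neurons, by 1.52 ± 0.06 and Ldb2 by 1.04 ± 0.07. Mef2c was at -1.06 ± 0.04 (835 against 1742 CPM), Lamp5 at -1.22 ± 0.09 and the potassium channel gene Kcnh5 at -2.03 ± 0.10. Of 8 deep-layer genes 7 were higher (8 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 2.0e-28, median log2 2.18) and all 5 upper-layer genes lower (5 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 1.3e-12, median log2 -1.22).

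Other neuronal lists split between the layers in RNA. Of 15 channel genes 4 were higher in deep-layer-like nuclei, with the calcium channel gene Cacna1e (0.16 ± 0.04). Another 4 were lower, with Kcnc2 (-1.69 ± 0.08), Kcnd2 (-0.28 ± 0.04) and Kcnq3 (-0.35 ± 0.04), the same numbers adjusted over the list alone. Of 12 glutamatergic readout genes 6 were lower, with Itpka (-0.94 ± 0.11), Mical2 (-0.25 ± 0.05) and Ptk2b (-0.26 ± 0.09). Another 3 were higher, with Baiap2 (0.30 ± 0.06) and Neurod2 (0.38 ± 0.13), or 6 and 4 adjusted over the list alone. Of 5 GABAergic readout genes Kcnc2 and Kcnc1 (-0.83 ± 0.17) were lower and Adarb2 (0.60 ± 0.12) and Grip1 (0.83 ± 0.08) higher, also adjusted over the list alone. Of 12 synaptic vesicle genes Stx1a (-0.82 ± 0.08) and Syn2 (-0.53 ± 0.07) were lower and 3 higher, with Cplx2 (0.29 ± 0.11) and Sv2a (0.23 ± 0.09), or 3 and 3 adjusted over the list alone. Of 3 cholesterol synthesis genes 1 was higher (1 adjusted over the list alone). Camera passed none of these 5 lists, with Benjamini-Hochberg adjusted p from 0.195 to 0.930 and median log2 from -0.19 to 0.31; medians and means differed in sign for the channel and synaptic vesicle lists. Oligodendrocyte readout genes, too low to test, were 2.04 times higher in upper-layer-like nuclei in sum (273 ± 19.98 against 133 ± 29.5 CPM, 12 of 12 libraries) and astrocyte readout genes 1.19 times (9 of 12).

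Chromatin also differed between the layers at lineage genes. Fezf2, which directs neurons to project below the cortex, was 2.08 ± 0.16 more open in deep-layer-like nuclei (54.5 against 12.8 CPM), followed by the kainate receptor gene Grik3 (1.80 ± 0.09), Map3k7cl (1.76 ± 0.18), Pcp4 (1.66 ± 0.12) and the nicotinic receptor gene Chrna4 (1.62 ± 0.18). Cux2, a homeobox gene of upper layers, was at -1.56 ± 0.07 (98.7 against 289 CPM). The other largest decreases were at Tmco2 (-2.24 ± 0.21, 7.85 against 37.9 CPM), Agxt2 (-1.61 ± 0.22), Car4 (-1.47 ± 0.21) and Zfhx4 (-1.43 ± 0.18), all in 12 of 12 libraries. Upper-layer markers were lower for 5 of 6 (5 adjusted over the list alone), with Cux2, Cux1 (-1.38 ± 0.06) and Rasgrf2 (-0.95 ± 0.07; camera, Benjamini-Hochberg adjusted p = 4.5e-36, 12 of 12 libraries). Deep-layer markers were higher for 4 of 6 (4 adjusted over the list alone), with Hs3st4 (1.59 ± 0.06), Bcl11b (1.46 ± 0.08) and Foxp2 (1.40 ± 0.10; camera, Benjamini-Hochberg adjusted p = 7.3e-30, 12 of 12 libraries). Of 11 deep-layer readout genes 9 were higher (9 adjusted over the list alone), with Thsd7b (0.94 ± 0.08), Ldb2 (0.65 ± 0.07) and Sox5 (0.63 ± 0.05). Of 10 upper-layer ones 6 were lower (8 adjusted over the list alone), with Lhx2 (-1.13 ± 0.12), Kcnh5 (-0.79 ± 0.10) and Mef2c (-0.16 ± 0.05). Their sums differed 1.66 times and 1.34 times in 12 of 12 libraries (camera, Benjamini-Hochberg adjusted p = 2.9e-22 and 7.1e-07).

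Over gene windows, oligodendrocyte and astrocyte markers were less open in deep-layer-like than in upper-layer-like neurons, while precursor markers went the other way in sum (1.101 times higher, 9 of 12 libraries; 1 of 4 higher and 0 lower, also adjusted over the list alone). Oligodendrocyte markers were lower for 3 of 4 (3 adjusted over the list alone), with St18 (-1.09 ± 0.18), Mobp (-0.94 ± 0.19) and Mbp (-0.14 ± 0.05; -0.13 and not past the test without library G), by camera at a Benjamini-Hochberg adjusted p = 0.0133 (median log2 -0.54, 12 of 12 libraries). Astrocyte markers were lower for 1 of 4, or 2 lower and 1 higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0163, median log2 -0.10, 12 of 12 libraries). Of 12 synaptic vesicle genes 3 were lower, Syn2 (-0.30 ± 0.07), Rab3a (-0.26 ± 0.08) and Stx1a (-0.23 ± 0.08), with 3 adjusted over the list alone. Without library G, Rab3a (-0.20) and Stx1a (-0.20) no longer passed. Camera passed no other list of gene windows (Benjamini-Hochberg adjusted p from 0.380 to 0.971). Some of these held higher and lower genes side by side, such as Slc6a11 (0.62 ± 0.12) with Gli3 (-0.78 ± 0.14) in the astrocyte readout, whose median (0.13) and test differed in sign. Of 15 channel genes 1 was higher and 3 lower, with Kcna2 (-0.45 ± 0.11) and Kcnc1 (-0.41 ± 0.08), or 2 and 5 adjusted over the list alone.

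By edgeR at a Benjamini-Hochberg adjusted p under 0.05, 1662 of 5898 genes passed in RNA (832 higher and 830 lower in deep-layer-like nuclei), 2768 of 12947 in chromatin (1348 and 1420) and 2709 of 13913 peaks (1258 and 1451). The largest peak increases lay in Cmya5 (chromosome 13, 93091728 to 93092500, mm10; 2.82 ± 0.22), outside genes (chromosome 11, 114257559 to 114258677; 2.78 ± 0.21) and in Slc39a11 (chromosome 11, 113335382 to 113336219; 2.57 ± 0.21). The largest decreases lay outside genes on chromosome 3 (142173759 to 142174445; -2.26 ± 0.24) and chromosome 4 (138525585 to 138526182; -2.17 ± 0.24) and beside Tmco2 (chromosome 4, 121103238 to 121103858; -2.21 ± 0.21). Peaks of upper-layer markers were lower for 6 of 7 (6 adjusted over the list alone), of upper-layer readout genes for 3 of 10 (4 adjusted over the list alone) and of astrocyte markers for 2 of 5 (3 adjusted over the list alone). Peaks of deep-layer markers were higher for 2 of 3 (2 adjusted over the list alone) and of deep-layer readout genes for 3 of 9 (3 adjusted over the list alone). Camera passed all of these 5 sets (largest Benjamini-Hochberg adjusted p = 0.0140). Peaks of oligodendrocyte markers did not pass, with 1 higher and 2 lower of 5, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.9804, median log2 0.02). With the deeper class thinned, 1760 genes in chromatin and 607 peaks passed, and DESeq2 called 1515 genes in chromatin.

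Genes that passed in both RNA and chromatin went mostly the same way, while over all tested genes signs matched for 59.6% (neurons), 70.7% (glia) and 63.0% (layers). Between layers 661 genes outside the clustering passed in both readouts: 280 were higher in both, where independent calls would give 83.4, 343 lower in both (90.0 if independent) and 38 opposite. Between neuron classes 649 passed in both, 120 higher (50.9 if independent), 475 lower (132 if independent) and 54 opposite. Between glial classes 11 passed in both, 7 higher and 4 lower in both readouts. Spearman's correlation of log2 differences across genes was 0.339 over 6523 genes for neurons, 0.594 over 116 genes for glia and 0.403 over 5560 genes for layers. Genes are not independent replicates, so these correlations carry no p-value.

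**Figure D2:**
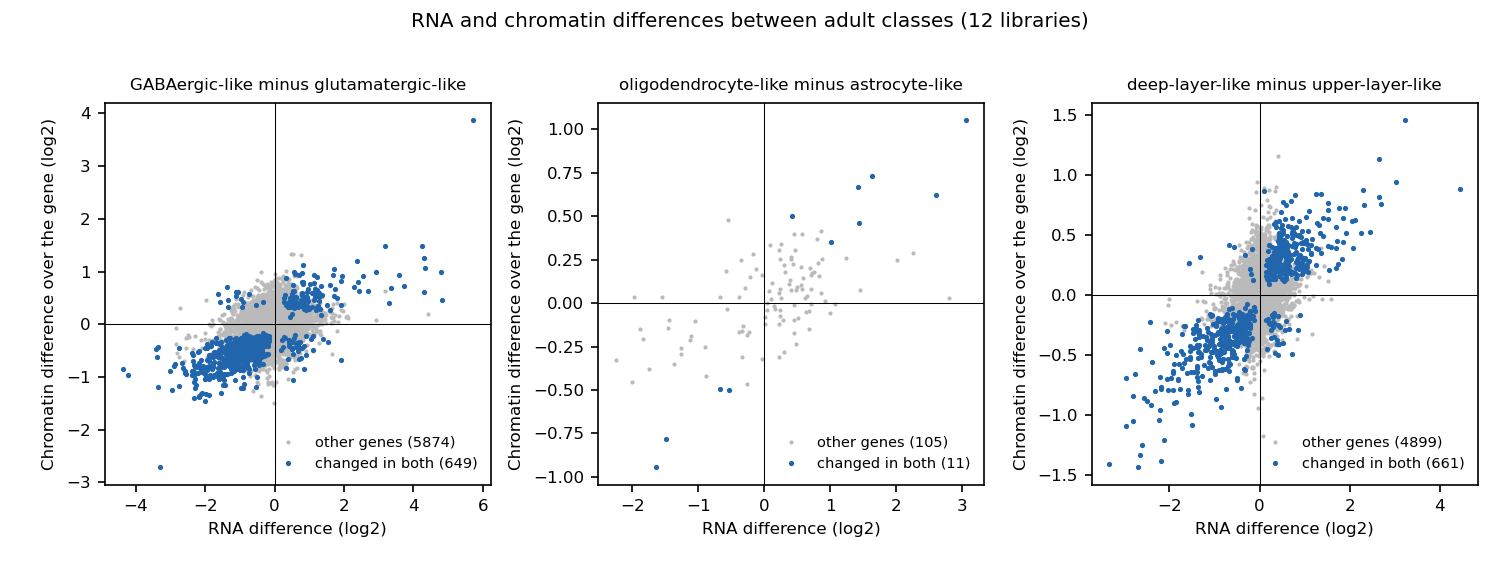
Log2 difference in RNA (horizontal) and in chromatin over the gene window (vertical) for genes outside the clustering, 1 panel per adult comparison and 1 point per gene. Blue points passed in both readouts, 649 for neurons, 11 for glia and 661 for layers, and most of them share the sign.

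At P0 the cortex still held dividing and migrating cells. Radial-glia-like nuclei made up 7.93% of 5081 nuclei (Wilson 95% interval 7.22 to 8.71), cycling-progenitor-like 4.19%, migrating-neuron-like 16.7%, upper-layer-like 14.3%, deep-layer-like 15.9%, GABAergic-like 6.18% (5.55 to 6.88) and Cajal-Retzius-like 0.945%, while 33.9% (32.6 to 35.2) took no name. Cell cycle genes were 3.67 times higher in cycling-progenitor-like than in migrating-neuron-like nuclei, the next class (2202 against 600 CPM, exact Poisson 95% interval 3.00 to 4.49). Progenitor genes were 1.66 times higher in radial-glia-like than in cycling-progenitor-like nuclei (9091 against 5466 CPM, 1.503 to 1.84), and genes of postmitotic neurons 1.78 times higher in the neuron classes than in the progenitor classes (13866 against 7779 CPM, 1.70 to 1.87). GABAergic readout genes were 4.27 times higher in GABAergic-like nuclei than in the next class (6111 against 1432 CPM, 3.54 to 5.18).

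Of 12 cell cycle genes 10 were highest in the cycling class, with the kinase gene Cdk1 (25.4 times, 6.37 to 220; 2 UMIs), Ccnb1 (23.5 times, 5.85 to 205; 2 UMIs) and the methyltransferase gene Ezh2 (1.58 times, 1.16 to 2.12), while Mcm6, with 3 UMIs, was at 0.402 times the radial-glia-like level with an interval that included 1 (0.0741 to 1.44). Of 12 progenitor genes 9 were highest in radial-glia-like nuclei, with the matrix gene Tnc (3881 CPM, 2.24 times, 1.88 to 2.68) and Ptprz1 (3795 CPM, 1.59 times, 1.36 to 1.86). Ccnd2 was not among the 9 and was level with the highest other class (0.968 times, 0.662 to 1.43). All 12 postmitotic genes were higher in the neuron classes, with the splicing factor gene Rbfox1 (2.38 times, 2.10 to 2.70) and the adhesion gene Nrxn3 (1.33 times, 1.195 to 1.49). Of 12 detected GABAergic genes 10 were highest in their class, with Adarb2 (4142 CPM, 8.60 times, 7.18 to 10.3). Sox6 (1.05 times) and Dlx1 (1.47 times, 0.836 to 2.66) were near the next class, and Npy was lower than in upper-layer-like nuclei (172 against 706 CPM, 0.243 times, 0.147 to 0.381).

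At P0 the layer lists were set against the highest other class, which was not the other layer. Upper-layer genes were 1.252 times higher in upper-layer-like than in migrating-neuron-like nuclei (5685 against 4539 CPM, 1.17 to 1.34), with 5 of 11 genes highest there. Among these 5, Mef2c was 1.29 times higher (1.17 to 1.43) and Limch1 1.17 times (0.889 to 1.54). The semaphorin receptor gene Plxna4 was lower than in the highest other class (0.863 times, 0.752 to 0.989). Deep-layer genes in deep-layer-like nuclei were at 0.875 times the level of the 48 Cajal-Retzius-like nuclei (2173 against 2483 CPM, 0.678 to 1.15). With TMM scaling they were at 1.247 times (0.966 to 1.63), and both intervals included 1. Most of the Cajal-Retzius-like sum came from 1 gene, Thsd7b, at 1436 CPM there against 84.5 in deep-layer-like nuclei. The list was not summed without it. Ldb2 (1.34 times, 1.07 to 1.68) and Zfpm2 (1.19 times, 0.828 to 1.75) were among the 7 of 12 genes highest in deep-layer-like nuclei, and Nfia was at 0.473 times the highest class (0.365 to 0.617). Chromatin clusters held 83.4% (79.4 to 86.7) of radial-glia-like nuclei in 1 cluster, 63.1% (57.6 to 68.2) of GABAergic-like, 50.7% of migrating-neuron-like, 45.2% of deep-layer-like and 40.7% of upper-layer-like nuclei, while 45.1% of cycling-progenitor-like nuclei shared the cluster of radial glia. The P0 table pools its replicates, so no test was made. At resolution 2.0 no cluster was named migrating neuron and 58.3% of nuclei took no name, and at a minimum of 500 UMIs deep-layer-like nuclei alone were named, 365 of 1229.

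**Figure D3:**
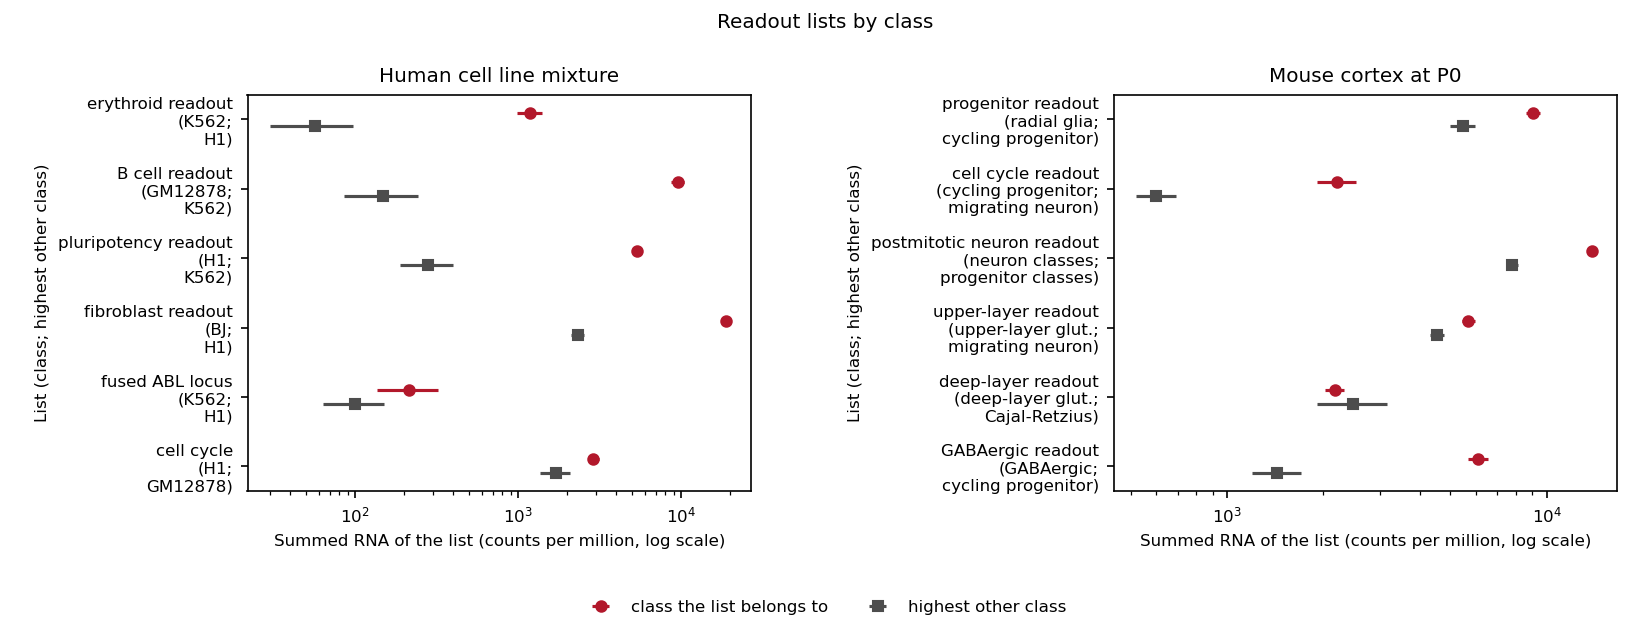
Summed level of each fixed list (CPM, log axis) in its own class and in the highest other class, for the cell line mixture and P0 cortex; bars are exact Poisson 95% intervals. B cell genes reached 9539 CPM in GM12878-like nuclei against 150, and deep-layer genes at P0 reached 2173 CPM in their class against 2483 in Cajal-Retzius-like nuclei.

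In glutamatergic-like neurons, immature neuron genes were higher and mature neuron genes lower at P0 than in the adult cortex (2 months). All comparisons of the ages are values with no test, since age is confounded with the table, the sequencing and the pooling. Immature neuron genes stood at 5437 CPM at P0 (exact Poisson 95% interval 5264 to 5615) and 1108 ± 47.7 CPM in the adult (mean ± SD, n = 12), 4.91 times higher, with 13 of 13 genes above every adult library. Mature neuron genes stood at 2254 CPM (2143 to 2370) against 9416 ± 252, 0.239 times, with 13 of 14 below every library. The microtubule regulator Stmn1 was 11.1 times higher at P0 (592 against 53.4 CPM) and the axon guidance receptor Robo2 2.16 times (1421 against 658 CPM). The calcium sensor Syt1 was at 0.305 times (1310 against 4292 ± 176 CPM) and Snap25, a protein of vesicle fusion, at 0.296 times (402 against 1356 ± 48.2 CPM). Tubb2b, with 952 CPM against 0.441 (6 adult UMIs), was 2158 times higher, but its level is uncertain, as how the counting treated near-identical tubulin genes was not stated.

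Receptor genes were lower at P0, with exceptions. Glutamate receptor genes stood at 0.585 times the adult level (7898 against 13496 ± 487 CPM), 10 of 14 below and 3 above every adult library. Grin2a, the NMDA receptor subunit of mature synapses, was at 0.130 times (212 against 1632 ± 104 CPM) and Grm7 at 0.302 times. Above were the AMPA receptor gene Gria2 (2777 against 1850 ± 54.9 CPM, 1.501 times) and Grin3a (71.6 against 26.6 ± 5.03 CPM, 2.69 times), a subunit of juvenile synapses. Genes of GABA receptors and chloride transport stood at 0.587 times (1876 against 3194 ± 145 CPM), 9 of 12 below and 1 above. Slc12a5, the chloride exporter that makes GABA inhibitory, was at 30.7 against 199 ± 19.8 CPM, Gabrb1 at 412 against 843 ± 60.8 and Gabrb2 at 245 against 424 ± 30.7. Gabra5 was above (90.6 against 58.6 ± 7.53 CPM). Myelin genes, made mainly by oligodendrocytes, were at 0.187 times (64.3 against 345 ± 50.8 CPM; 4 of 6 below), with Mbp at 29.2 against 275 ± 44.9 CPM, Mag at 0 UMIs against 14.7 CPM and Mog at 10.2 against 7.60 CPM.

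Fetal growth and chromatin genes were higher at P0. The list of fetal IGF and RNA-binding genes stood at 2.01 times the adult level (386 against 192 ± 15.0 CPM; 4 of 6 above and 1 below), with Igf2bp3 (5.57 times) and the receptor gene Igf1r (1.61 times) above and Lin28b lower (13.1 against 27.9 CPM). DNA methylation and chromatin genes stood at 1.53 times (1781 against 1166 ± 23.8 CPM; 9 of 14 above and 2 below), with the remodeller genes Smarca4 (2.19 times) and Smarca2 (1.49 times) and the Polycomb gene Ezh2 (247 against 27.5 CPM) above. Dnmt3a, which methylates neuronal DNA after birth, was at 0.386 times (96.4 against 250 ± 13.8 CPM). GABAergic-like neurons had the same directions: immature genes 4.07 times (5214 against 1282 ± 143 CPM), mature genes 0.331, glutamate receptors 0.683, GABA receptors 0.534, fetal genes 2.34, chromatin genes 1.51 and myelin 0.0863 times (4 UMIs). Over all nuclei the ratios were 5.47, 0.213, 0.575, 0.532, 1.98, 1.57 and 0.124 in the same order.

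**Figure D4:**
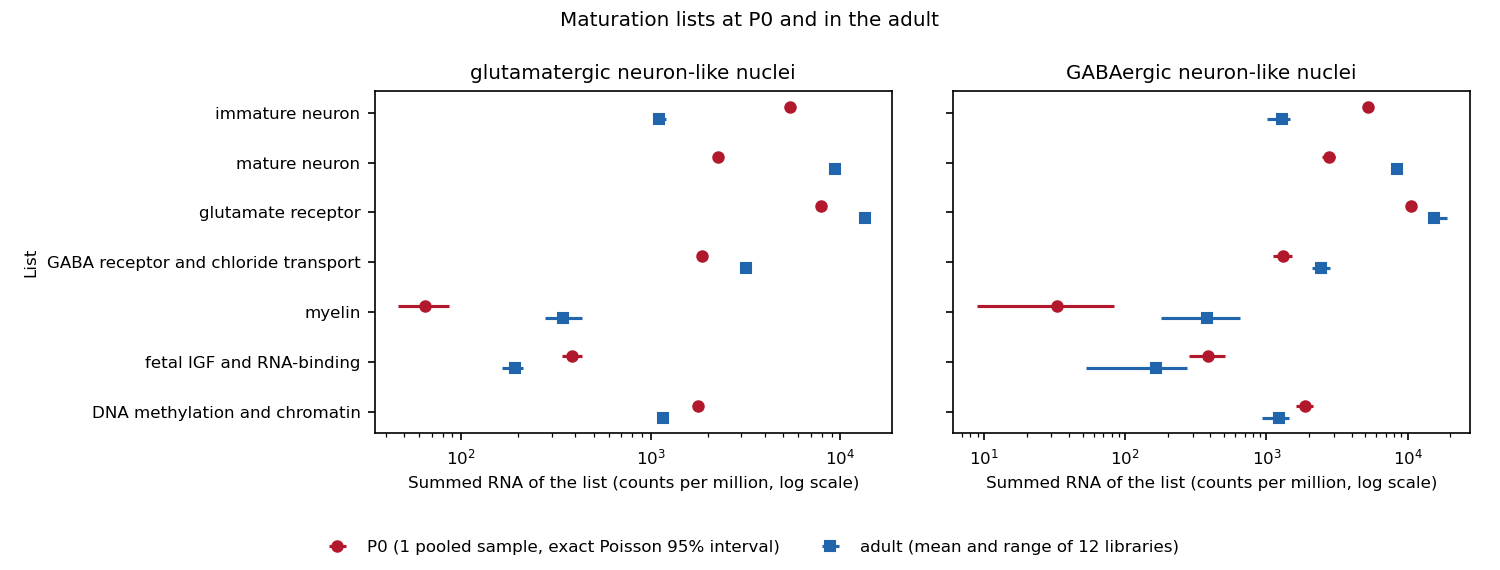
Summed level of 7 fixed lists (CPM, log axis) in glutamatergic-like and GABAergic-like neurons: P0 pool with exact Poisson 95% interval beside the adult mean with the range of 12 libraries. Immature neuron genes lie at 5437 against 1108 CPM and mature neuron genes at 2254 against 9416 CPM in glutamatergic-like neurons.

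Of 10805 genes with at least 100 UMIs, 4221 lay above and 3215 below every adult library. A further library like the 12 would lie beyond them for 7.69% of genes on each side. The P0 pool is not such a library. It comes from another table and held 684514 UMIs of glutamatergic-like neurons, against 950268 to 1413364 per adult library. The rate is therefore no test of these counts. After Tubb2b the highest ratios belonged to Cd24a (425 times, with 6 adult UMIs), the neuropeptide gene Npy (368 times, 586 against 1.59 ± 1.39 CPM), Igfbpl1 (114), Marcksl1 (102), the sialyltransferase gene St8sia2 (67.7), Gipr (64.8), Nnat (63.5), Tuba1a (62.1; uncertain for the same reason) and Tubb5 (48.0). The highest adult to P0 ratios belonged to Rasgrf1 (283, interval 50.8 to 11178; 1 P0 UMI), Car10 (254; 5.84 against 1484 ± 78.9 CPM), Aifm3 (145, 40.1 to 1195; 2 UMIs), the noncoding RNA Snhg11 (111; 78.9 against 8771 ± 446 CPM), Icam5 (106, 18.97 to 4175; 1 UMI), Itpka (91.1, 16.4 to 3597; 1 UMI), Kcnj9 (86.2, 15.5 to 3403; 1 UMI), Sidt1 (83.2, 23.0 to 687; 2 UMIs), the vesicular zinc transporter gene Slc30a3 (81.3, 14.6 to 3213; 1 UMI) and Dlgap3 (64.5, 11.6 to 2548; 1 UMI). Of P0 peaks 42.3% overlapped an adult peak and held 89.0% of P0 counts, and 39.8% of adult peaks, with 70.4% of adult counts, overlapped a P0 peak. With a reciprocal overlap of 50% the P0 share was 29.2% and the adult share 27.4%. For peaks with counts in at least 50 nuclei the P0 share rose to 74.3% and the adult share fell to 34.0%. Peaks were called separately and covered 87.1 Mb at P0 and 102 Mb in the adult, with median widths of 300 and 362 bases. Age is confounded with the table, the sequencing and the pooling, so these are values with no test.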

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

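Both results here were found by a comparison chosen only after the P0 and adult levels had been seen, and the difference between the ages was not tested. Among 139 readout genes with at least 20 P0 UMIs, 55 differed between GABAergic-like and glutamatergic-like neurons in the same direction in all 12 adult libraries, and 2 of these had the opposite direction at P0. The neuropeptide gene Npy was higher in adult GABAergic-like neurons in 12 of 12 libraries (197 ± 80.0 against 1.58 ± 1.38 CPM), while at P0 it stood in GABAergic-like neurons at 0.293 times the glutamatergic-like level (exact conditional 95% interval 0.179 to 0.454). The splicing factor gene Rbfox1 was higher in adult GABAergic-like neurons in 12 of 12 libraries (3001 ± 272 against 2352 ± 117 CPM) and at P0 stood at 0.8398 times (0.734 to 0.957).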

How the results depend on the processing

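Tests chosen only after the results were seen are those without library G, those with counts thinned to the smaller class, and the swaps of class labels within libraries. Of 102 counts and summary values under alternatives 80 stayed within their margin (1.5 times for a count, the spread or interval for a value) and 22 moved. Of 1723 values of named genes and peaks 1645 kept direction and side of the threshold, 76 kept the direction and no longer passed, and 2 reversed. Genes called in both fits had the same direction in every alternative, except for peaks without the filter on low counts (3388 of 3673 for neurons and 1656 of 1661 for layers).

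Thinning counts to the smaller class left 605 genes in RNA, 804 gene windows and 3 peaks for neurons, 43 windows and 2 peaks for glia, and 1760 windows and 607 peaks for layers; fewer features were then tested. Without the filter on low counts, which tests many more features, 64994 peaks passed for neurons, 535 genes, 379 windows and 394 peaks for glia and 30179 peaks for layers. In that fit of neuron RNA the median of all genes was -0.44, and Sox5 (-0.00846, adjusted p = 0.960 by edgeR with Benjamini-Hochberg) and Syn2 (-0.0135, adjusted p = 0.937 by edgeR with Benjamini-Hochberg) reversed without passing. DESeq2 called 31 windows for glia and 1515 for layers, and for these the cause was not tested. Glia peaks numbered 2 at a minimum of 500 UMIs and 0 of 19 tested with counts above 1 set to 1 (edgeR; 3 at an unadjusted p under 0.05; no other tool was run on peaks). The glutamatergic-like share was 77.2% at a minimum of 500 UMIs, where 9.50% of nuclei took no name. At resolution 0.5 the adjusted Rand index was 0.582 ± 0.0279, with fewer clusters. The median log2 ratio of the P0 lists was 0.94 with TMM scaling against 0.78, and the cause was not tested. The share of P0 peaks that overlapped an adult peak was 29.2% when 50% of both peaks had to overlap and 74.3% for peaks seen in at least 50 nuclei. The share of adult peaks was 27.4% and 34.0%, both below the main 39.8%. The reciprocal rule lowers both shares by construction. For the rule of 50 nuclei, which moved the shares in opposite directions, the cause was not tested.

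Fry passed 62 lists where camera passed 33, since it asks a different question. All 29 gains were by fry and all 5 losses by camera with an estimated correlation. With no library block, that is, without pairing the classes of a library, edgeR called 1839, 3061 and 5168 features for neurons (RNA, windows, peaks), 152, 63 and 3 for glia and 1586, 2559 and 2542 for layers. Without library G the counts were 1675, 2704 and 4302, then 148, 76 and 4, then 1579, 2628 and 2629. Calls lost by setting numbered 21 with DESeq2, 19 with thinning, 8 without the filter, 7 at a minimum of 500 UMIs, 6 without library G and 4 with counts above 1 set to 1. In the first fit these were at an absolute log2 of 0.86 or less, such as Mef2c between layers in chromatin (-0.16 with DESeq2), Mical2 between neurons in chromatin (-0.09 with thinning) and Cplx2 between layers in RNA (0.20 without the filter). The lower glial peak in Garem was lost in 7 settings. With RLE factors the neuron peaks split 589 to 4665, with the median of all peaks at -0.19.

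Swapping class labels within libraries (50 swaps, the real labels included) left the real labels as the only 1 with so many calls in all 9 fits. This argued against chance for the gene windows of glia, where depths of the classes overlapped (31860 to 74045 and 39586 to 101230 counts). For chromatin of neurons and layers the swaps could not decide, since a swap also mixed sums of unlike depth. For neuron peaks these held 67104 to 165400 against 1603800 to 2203400 counts, and for layer peaks 318800 to 539610 against 750820 to 1184600. Thinned to equal depth, 3 of 753 neuron peaks, 804 of 3605 neuron windows, 607 of 6961 layer peaks and 1760 of 10547 layer windows passed. Classes made from RNA were bound to give more calls in the 3 RNA fits, where the swaps decide nothing. The real counts were 1764, 2952 and 4643 for neurons, 155, 66 and 4 for glia and 1662, 2768 and 2709 for layers, and the highest others 179, 294 and 53, then 70, 19 and 3, then 184, 546 and 442. For glial peaks the margin was narrow, 4 against 3, so the swaps could not exclude chance there. The highest others came from swaps of only 2 libraries.

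Peaks within 2 kb of a transcription start alone were not run, since the annotation holds no strand. At a minimum of 500 UMIs the P0 lists and the GABAergic-like age lists had no value, since most P0 clusters took no name, and P0 had no fit with doublets kept because none were removed. Among the adult fits, glial peaks had the fewest features with the counts to be tested, 102. Depth also limits P0 layers, as nuclei had a median of 357 UMIs.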

Other observations

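All tests here were chosen only after the result was seen, except those of signal in wide peaks, of chromatin at immediate early genes and of chromatin at Npy, whose bounds were written before. Some genes went opposite ways in RNA and chromatin between GABAergic-like and glutamatergic-like neurons, and were picked after their values were seen. The adhesion gene Cdh9 was higher in RNA (1.63 ± 0.12, 12 of 12 libraries) and less open (-0.93 ± 0.25, 11 of 12), as were the collagen gene Col11a1 (2.14 ± 0.19 and -0.74 ± 0.26) and Zfp804b (1.52 ± 0.09 and -1.11 ± 0.23). Cdk9, a kinase of transcription elongation, was lower in RNA (-1.62 ± 0.20) and more open (0.58 ± 0.15). Between layers Reln, an extracellular guidance protein, was higher in deep-layer-like RNA (0.77 ± 0.14) and less open (-0.49 ± 0.08).

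Immediate early genes, which neuronal activity or handling switches on within minutes, led 1 RNA cluster of 273 upper-layer-like nuclei. The list of 10 (Fos, Fosb, Junb, Egr1, Arc, Npas4, Nr4a1, Dusp1, Btg2 and Ier2), drawn up after the cluster was seen, stood at 4292 ± 411 CPM there and 398 ± 48.6 CPM in the other upper-layer-like nuclei (n = 12). A single library was excluded as the source, as every library held at least 15 nuclei of the cluster (2.68% ± 0.780 of nuclei). Doublets were argued against by a median UMI count 0.920 times that of the other nuclei. Handling that raised these genes alike in every class stays open: GABAergic-like nuclei had at most 0.468 times the upper-layer-like level in any library, but deep-layer-like nuclei had 622 ± 137 CPM and microglia-like ones 396 ± 374, and no class has a baseline here. Chromatin over the 10 gene windows (41 peaks) was 1.499 times higher in the cluster (1403 ± 209 against 933 ± 44.2 CPM, 12 of 12 libraries; two-sided sign-flip permutation p = 0.000488, the smallest 12 pairs can give). Whether activity or handling switched them on cannot be told apart.

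Chromatin clusters of adult library G stood apart at resolution 1 while its RNA did not (deviation from the other libraries 0.183, within their 0.163 to 0.207). In it 16.6% of deep-layer-like and 6.68% of upper-layer-like nuclei were in the leading chromatin cluster of their class, against 70.9% ± 3.02 and 37.0% ± 2.09 in the other 11. Lower depth was argued against, as 5 of 11 libraries had a lower median, and mispaired barcodes too, as 93.5% of its GABAergic-like nuclei were in the leading cluster of that class (93.9% ± 3.15 in the others). More signal in wide peaks is a candidate explanation, as the widest held 45.6% of its counts (42.3% ± 0.246 in the others). The SD of its log2 deviation over strong peaks, 0.295 (at most 0.209 in the others), only restates that it stood apart. What made that spread is open, and no biological explanation was tested, since the design gives none.

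Npy, which adult interneurons make, was high in P0 glutamatergic-like neurons (586 CPM against 1.59 ± 1.39 in the adult), with a UMI in 13.1% of upper-layer-like nuclei (median 367 UMIs) and 1.89% of migrating-neuron-like ones (median 324 UMIs). RNA from GABAergic nuclei was argued against, since the ratio of Npy to Gad1 plus Gad2 was 120 times higher in glutamatergic-like than in GABAergic-like nuclei (21.1 against 0.176). This covers only stray RNA with the mean ratio of the GABAergic-like nuclei, and P0 doublets were not removed. A factor on Npy in 1 table was excluded as the whole source, since it would leave the ratio of GABAergic-like to glutamatergic-like level unchanged. That ratio was 0.293 at P0 (0.179 to 0.454) and at least 34.5 in each adult library (3 libraries without a glutamatergic-like UMI at a floor of 3). Chromatin at Npy (chromosome 6, 49822710 to 49829507, mm10; 3 peaks) was 1.005 times as high in glutamatergic-like as in migrating-neuron-like nuclei, with an interval of 0.602 to 1.71 (44 and 25 counts). The bound written before the test against more open chromatin, an interval that includes 1, was met. That bound was wrong, since the interval also includes the 1.5 times that open chromatin was to show, so the test could not decide. Age stays open as an untested explanation, and P0 pools its replicates.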
